A study of Mus musculus with 15 samples.

How the data were processed

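Bulk RNA was sequenced from mouse liver as 15 libraries after 8 weeks of high-fat diet, per the labels. They were 5 wild-type (WT) libraries, 5 with the TXNIP C247S change (C247S KI) and 5 Txnip knockout (KO) libraries. TXNIP is the thioredoxin-interacting protein, which binds thioredoxin and restrains glucose uptake. Groups and replicate numbers were taken from the sample titles. The labels do not say in so many words that each library came from its own animal, so p-values measure the spread between these libraries.

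The deposited table holds estimated counts per transcript as whole numbers, which the authors made with kallisto 0.50.1 after trimming with Trimmomatic 0.39, per the submitters' processing notes. These notes also name DESeq2 and the mm10 build; the transcript set is not given in the sources used here. The totals lay between 18047577 and 23379940 estimated counts per library, and totals of this range leave counting error small beside the spread between libraries for all but the lowest genes. Because the deposited values are estimated counts, reads that match several transcripts had been divided among them before deposit, and genes with near-identical copies are uncertain for that reason. A transcript-level estimate does not show which exons the reads came from.

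Transcripts were matched to GENCODE release M21 (GRCm38) by identifier without version, and 114331 of 115911 matched (98.64%). Only 13 matched transcripts carried the same version number as that release. The 1580 unmatched transcripts held 0.366% to 0.459% of the counts of a library and stayed out of library sizes and gene tests. Matched counts were summed to 35546 genes, with 30 gene identifiers merged into an overlapping locus of the same symbol. The values were already whole numbers, so rounding changed nothing.

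Genes were kept with filterByExpr by group (minimum count 10, minimum total count 15), which left 13916 genes. All 15 libraries entered one fit with edgeR 4.0.16 in R 4.3.3: TMM factors, a group-means design and the quasi-likelihood test (glmQLFit, glmQLFTest), with Benjamini-Hochberg adjusted p below 0.05 as the threshold. The standard error (SE) of a log2 fold change was its size over the root of the F statistic. Values per library are counts-per-million (CPM) scaled by the TMM factors, and log2 CPM used a prior count of 2. For Txnip an exact two-sided permutation test on log2 CPM was added.

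The tests, the rule for named genes and 39 gene lists were fixed before the data were examined, and 38 lists had at least 3 tested genes. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation and with fry. The rule named Txnip, then the 6 largest rises and the 6 largest falls among genes past the threshold with a mean of at least 1 CPM in 1 of the groups and no overlap between the 5 libraries of each group, leaving out predicted gene models. It then named up to 3 called members with the lowest p of each list, of which the text may leave out those beyond 1 per list. From insulin signalling, gluconeogenesis, lipogenesis and thioredoxin system lists with no called member it took up to 2 members with the lowest p, given as values.

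The procedure was tested on simulated counts with the means, library sizes and dispersions of these libraries and 200 changed genes. At 3-fold, 82% of changed genes were recovered in the simulated C247S KI against WT comparison (13729 genes), 88% in KO against WT (13741 genes) and 83% in KO against C247S KI (13745 genes). At 1.5-fold the shares were 19%, 17% and 22%. False calls numbered 7, 7 and 5. In a simulation with the cholesterol synthesis list raised 1.5-fold in KO, camera called that list and 0 of the others. Simulated genes varied independently of each other, whereas the real list had an estimated correlation of 0.546 in KO against WT. The simulation therefore does not test camera on lists whose members vary together.

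The alternatives set beforehand were DESeq2 1.42.0 with its default independent filtering, limma-voom (limma 3.58.1), RLE and upper-quartile factors, no count filter, a mean count of at least 50, a fit of only the 2 groups compared, the replicate number as a block, 1 surrogate variable (sva 3.50.0), a test against a fold of 1.2, and leaving out each library. A sex covariate was not run because all 15 libraries held reads of Y-linked genes and Xist did not pass the count filter. Other splits of the libraries were drawn 100 times per comparison. A clock index covariate and a fit without WT 1, C247S KI 3 and C247S KI 5, taken as libraries that stand apart, were added after seeing the data. KO 5 was kept in that fit, although it lay at 38.7 on the second principal component, beside 35.57 for C247S KI 5. The clock index was the mean log2 CPM of 5 clock genes, which included Dbp and Ciart, less that of 4 others, which included Arntl. It was 1.46 to 2.62 in WT, 0.24 to 1.90 in C247S KI and 2.62 to 3.55 in KO libraries. Because it nearly followed the KO genotype, a fit with it cannot part clock phase from genotype. The values of Dbp, Ciart and Arntl are adjusted by an index that they make up. Each library was counted as a replicate by its label. Same-group libraries differed by more than counting noise (chi-square per degree of freedom 22.8 to 368.5 over 30 pairs), so no library was a copy of another, which does not show that they came from separate animals. Exact tests and figures used Python 3.11.15 with scipy 1.17.1 and matplotlib 3.10.9.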

Results

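Liver transcripts were measured by bulk RNA sequencing in 15 mouse libraries, 5 each of WT, C247S KI and KO, after 8 weeks of high-fat diet. The C247S change replaces the cysteine through which TXNIP binds thioredoxin. The series asks, by its title, whether that bond is needed for insulin resistance of the liver under the diet. The libraries held 18047577 to 23379940 estimated counts and 13916 genes were tested. The first principal component took 23.6% of the variance and separated the 5 KO libraries (18.61 to 44.69) from the 10 others (-42.11 to 0.03).

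Txnip, on chromosome 3 from 96557957 to 96561883 in GRCm38 (ENSMUSG00000038393), was reduced but still measured in the KO libraries. Its mean was 222 ± 56.2 CPM in WT, 192 ± 65.7 in C247S KI and 99.0 ± 24.9 in KO (SD, n = 5 each). Txnip fell by 1.17 on the log2 scale in KO against WT (SE 0.24, edgeR quasi-likelihood adjusted p = 0.00886), with all 5 KO libraries below all 5 WT libraries, and the exact permutation p of 0.00794 is the smallest that 5 against 5 allows. Against C247S KI it fell by 0.96 (SE 0.24, edgeR adjusted p = 0.0182; exact permutation p = 0.0317), where C247S KI 3, at 99.9 CPM, lay within the KO range, and that adjusted p was 0.0576 without KO 4, 0.0560 against a fold of 1.2 and 0.496 with a clock index as a covariate, an alternative added after seeing the data. In C247S KI against WT the log2 difference of Txnip was -0.21 (SE 0.24, edgeR adjusted p = 0.782). Both protein-coding transcripts kept reads in every KO library, 835 to 1449 counts of ENSMUST00000074519 and 549 to 1190 of ENSMUST00000049093. Estimates per transcript cannot show whether an exon is missing from these reads, so the Txnip level alone does not define the deletion.

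**Figure D1:**
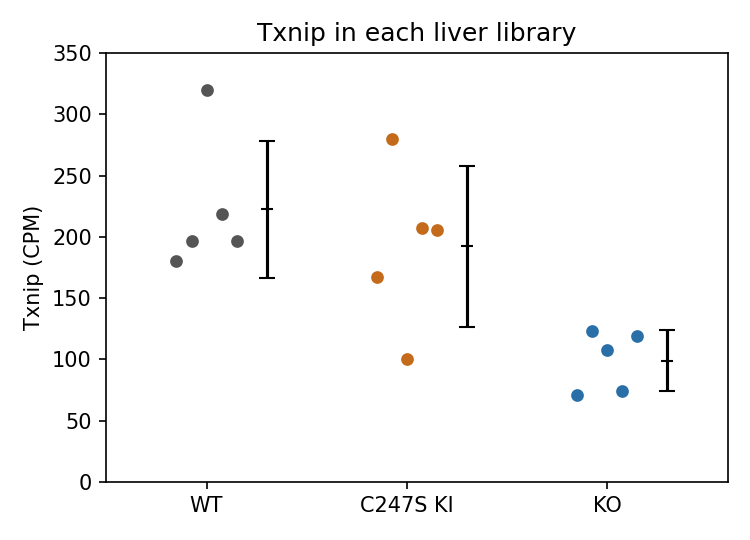
Txnip in CPM (vertical axis) for each of the 15 libraries by genotype; points are libraries and bars show the mean and SD of 5. KO libraries lie between 70.9 and 123.5 CPM, below the WT libraries, and C247S KI 3 lies at 99.9.

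In C247S KI livers, genes of cholesterol synthesis were higher than in WT. Sqle, the squalene epoxidase, rose by 2.70 (SE 0.38, 85.9 ± 35.3 against 13.2 ± 6.48 CPM, SD, n = 5 each), Nsdhl by 1.55 (SE 0.23) and Hsd17b7 by 1.12 (SE 0.18), with edgeR adjusted p of 0.00507, 0.0101 and 0.0207. Cyp51 (1.64), Dhcr7 (1.07) and Tm7sf2 (0.95), which act in the same pathway and were named after their values were seen, rose too. Of the 25 members 6 rose and 0 fell over all genes tested, 20 rose when adjusted over the list alone, and 23 had a positive log2 change. Without WT 3 the calls of Nsdhl, Hsd17b7, Cyp51, Tm7sf2 and Dhcr7 were lost (edgeR adjusted p = 0.0584 to 0.137), and Sqle kept its call. The list passed camera (adjusted p = 2.79e-37) and fry (adjusted p = 0.0467), and its camera call was lost with adjusted p = 0.0828 with an estimated correlation.

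Only 12 genes passed the threshold between C247S KI and WT in the edgeR test, 9 higher and 3 lower, against 1370 at an unadjusted p under 0.05. Amd2, an intronless S-adenosylmethionine decarboxylase gene, rose by 3.66 (SE 0.50) and Grk3, a G protein-coupled receptor kinase, by 1.31 (SE 0.23). Amd2 resembles Amd1, so its reads are uncertain. Krt23, a keratin, fell by 2.16 (SE 0.39), and Cyp2b13, a female-biased cytochrome P450, fell by 4.64 (SE 0.78) to 0.315 CPM, although WT 1 was at 0.311 CPM and the groups overlapped. The remaining pair were mt-Nd3, a complex I subunit of the mitochondrial genome (chromosome M, 9459 to 9806), which rose by 1.57 (SE 0.14, 607 ± 51.9 against 205 ± 30.3 CPM, SD, n = 5), and Gm28438, an unprocessed pseudogene on chromosome 1 (24612775 to 24613119) and a near copy of mt-Nd3, which was named after its values were seen and fell by 4.63 (SE 0.22). The sum of mt-Nd3 and Gm28438 differed between C247S KI and WT by -0.03 on the log2 scale, so both values are uncertain.

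**Figure D2:**
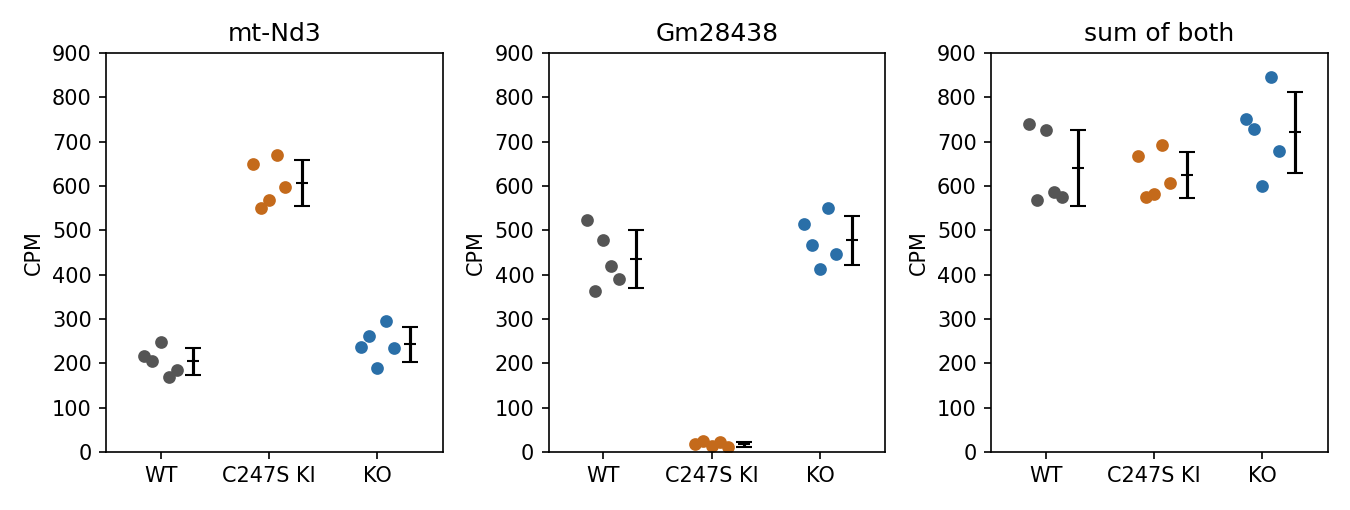
CPM (vertical axes) of mt-Nd3, of Gm28438 and of their sum for each of the 15 libraries by genotype; points are libraries and bars show the mean and SD of 5. Gm28438 lies at 10.5 to 24.5 CPM in C247S KI and at 364 or more in the WT and KO libraries.

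No member of the insulin signalling, gluconeogenesis, lipogenesis or thioredoxin system lists passed the threshold in C247S KI against WT, with edgeR. The lowest p values belonged to Igfbp1 (0.83, SE 0.27, adjusted p = 0.341) and Trib3 (-0.88, SE 0.30, adjusted p = 0.372) in insulin signalling, and to Creb3l2 (0.48, adjusted p = 0.350) and Pck2 (0.52, adjusted p = 0.368) in gluconeogenesis. In lipogenesis they belonged to Acss2 (214.6 against 107.5 CPM, adjusted p = 0.288) and Elovl6 (0.83, adjusted p = 0.316), and in the thioredoxin system to Txn1 (-0.40, adjusted p = 0.363) and Glrx5 (-0.29, adjusted p = 0.499). Adjusted over the list alone, 2 lipogenesis genes rose and 1 fell, and 0 genes of the other 3 lists passed. Under other settings Acss2 passed with DESeq2 (adjusted p = 0.0456), and Elovl6 passed without C247S KI 3 (adjusted p = 0.0458) and without WT 1, C247S KI 3 and C247S KI 5 (adjusted p = 0.00508), the last chosen after seeing the data. Camera called 11 of 38 lists, 4 higher and 7 lower. Beside cholesterol synthesis, those higher were cholangiocyte markers (9 of 9 positive, 3 higher adjusted over the list alone; adjusted p = 0.000461), mitochondrial-genome oxidative phosphorylation (0.000108), which holds mt-Nd3, and male-biased genes (0.0120). Those lower were the thioredoxin system (adjusted p = 0.000813), NRF2 targets (0.00228), xenobiotic metabolism (5.45e-07), nuclear oxidative phosphorylation (1.47e-08), fibrosis markers (0.0217), Kupffer cell and macrophage markers (5.45e-07) and sinusoidal endothelial markers (0.000461). None of the 11 passed with an estimated correlation, where those 10 lists had an adjusted p of 0.5085 to 0.7811. The calls of the NRF2, fibrosis, male-biased and endothelial lists were also lost without at least 1 library, with adjusted p of up to 0.5175 for the male-biased list without C247S KI 3. The endothelial call was lost with the clock index, and those of the thioredoxin system and nuclear oxidative phosphorylation without WT 1, C247S KI 3 and C247S KI 5, both added after seeing the data. The count of 12 depended on the libraries and the method: 4 without WT 3, 5 without WT 4, 7 without C247S KI 1 and 24 without C247S KI 4, and 65 with DESeq2. Of the 12 genes, Nsdhl, Grk3, Hsd17b7, Krt23, Cyp2b13, Cyp51, Tm7sf2 and Dhcr7 lost their call without at least 1 library, with the highest adjusted p for Krt23 without WT 3 (0.148), and each library except C247S KI 4 ended at least 1 of these calls. Without WT 1, C247S KI 3 and C247S KI 5 Sqle lost its call too (2.39, adjusted p = 0.0770), as did Nsdhl, Grk3, Hsd17b7, Krt23, Cyp51 and Dhcr7. Grk3, Hsd17b7, Krt23, Cyp2b13, Cyp51, Tm7sf2 and Dhcr7 also lost theirs under at least 1 other alternative set beforehand, such as a fit of only the 2 groups, and Amd2, mt-Nd3 and Gm28438 kept theirs in every fit run for them.

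In KO livers, genes of fatty acid synthesis and lipid storage were lower than in WT. Scd1, the stearoyl-CoA desaturase, fell by 3.82 (SE 0.46, 266 ± 123 against 3745 ± 852 CPM, SD, n = 5 each, edgeR adjusted p = 0.000332), Acacb, an acetyl-CoA carboxylase, by 1.92 (SE 0.31) and Elovl5, a fatty acid elongase, by 2.02 (SE 0.37). Cidec, a lipid droplet protein, fell by 3.77 (SE 0.67), and the log2 changes of Cd36, a fatty acid transporter, Fabp4 and Hsd17b13 were -1.99 (SE 0.33), -1.40 (SE 0.17) and -1.06 (SE 0.15). Pdk4, which inhibits pyruvate dehydrogenase, fell by 3.83 (SE 0.61), but with a clock index as a covariate, added after seeing the data, it was at -2.30 and did not pass (adjusted p = 0.224). Apoa4, an apolipoprotein of the periportal list, fell to 258.9 from 2068 CPM. Of 20 lipogenesis genes 7 fell and 0 rose (14 fell adjusted over the list alone; camera adjusted p = 1.63e-08), and of 20 lipid droplet and steatosis genes 8 fell and 0 rose (13 adjusted over the list alone; 3.47e-09). Both camera calls were lost, each with adjusted p = 0.274 with an estimated correlation. Both lists passed fry (adjusted p = 0.0204 and 0.0164). Cidec and Fabp4 also belong to the adipose tissue markers, of which 3 of 5 were lower and 1 higher (the same count adjusted over the list alone; camera adjusted p = 0.0115, and 0.274 with an estimated correlation).

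Across the genome 939 genes passed the edgeR threshold in KO against WT, 356 higher and 583 lower. Genes with male-biased liver expression were higher: Susd4 rose by 1.83 (SE 0.21), Cyp4a12b by 3.14 (SE 0.54) and Cyp7b1, also of the bile acid synthesis list, by 2.15 (SE 0.44). Of 19 male-biased genes 6 rose and 0 fell (13 rose and 2 fell adjusted over the list alone; camera adjusted p = 3.47e-09). Of 10 female-biased genes 5 fell and 0 rose (the same count adjusted over the list alone; camera 0.000178), among them Hao2 (-4.78), Cyp2a4 (-4.24) and Cyp2b13 (-4.67). With an estimated correlation both had adjusted p = 0.274. Outside these lists Mup14 and Mup12, urinary protein genes of a family with near-identical members, rose by 2.46 and 2.25. Cyp2a22 (-6.18, SE 0.91) and Gsta1 (-5.40, SE 1.06) had the largest falls among genes named by the rule, and both belong to families of similar genes. The KO means of Cyp2a22, Gsta1, Hao2 and Cyp2b13 were 0.322, 0.173, 0.101 and 0.327 CPM, so the sizes of their falls are uncertain. For Cyp2b13 the level of WT 1 lay below that KO mean, so the KO and WT libraries overlapped.

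Hist1h2al, a processed pseudogene of the histone H2A family on chromosome 13 (51202727 to 51203065), had the largest rise among the 939 genes that passed, by 6.83 (SE 0.35, 7.37 ± 1.59 CPM against 0.0599 in WT), and its reads are uncertain because histone genes have similar sequences. The WT libraries held so few counts of Hist1h2al that the size of its rise depends on the prior count. Serpina9 rose by 3.39 (SE 0.68) and Plcd3, a phospholipase C, by 2.38 (SE 0.39). Serpina9 was at 0.137 CPM in WT, so the size of its rise is uncertain too. Nnt, the mitochondrial transhydrogenase that differs between substrains of C57BL/6 mice, rose by 1.05 (SE 0.14) to 120 CPM. Of 4 genes listed as differing between mouse substrains Nnt was the 1 that passed over all genes. Adjusted over the list alone, 2 were higher and 2 lower. Camera did not call that list (adjusted p = 0.267) and fry did (adjusted p = 0.0243). In C247S KI against WT 0 of the 4 passed over all genes, and 1 was higher and 1 lower adjusted over the list alone. Beside Txnip, Acp6 rose by 0.55 and Hfe2 fell by 0.75. Within 5 Mb of Txnip 17 of 109 genes passed the threshold (15.6%) against 6.7% elsewhere (Fisher's exact p = 0.00145, window chosen after values were seen), within 2 Mb 10 of 79 did (12.7%, exact p = 0.0431), and within 10 Mb the share was 8.9% (exact p = 0.198). The 17 include the clock gene Ciart and the female-biased gene Hao2, and the exact test treats genes as independent of each other.

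Camera called the cell cycle, inflammation, NRF2 target and fibrosis lists lower in KO than in WT, although most of their members did not pass the threshold. Cdkn1a, the cell cycle inhibitor p21, fell by 2.77 (SE 0.34), Ccnd1, cyclin D1, by 1.45 (SE 0.19), Il1rn, the interleukin-1 receptor antagonist, by 1.35 (SE 0.16), and Cxcl1, a chemokine, by 2.90. Il1rn and Cxcl1 were the 2 of 27 acute-phase and inflammation genes that passed (5 lower adjusted over the list alone; camera adjusted p = 0.000178, and 0.274 with an estimated correlation). Atf3 of the stress response list changed by -2.67, and Col4a1 and Sparc of the fibrosis list by -1.06 and -0.71. Of 23 NRF2 targets 7 fell, among them Gstm3 (-1.82) and Hmox1 (-0.94), and 0 rose (12 fell adjusted over the list alone; camera adjusted p = 6.42e-07). Fibrosis and stellate cell markers had 3 of 22 lower (7 adjusted over the list alone; camera 1.005e-06) and cell cycle genes 3 of 22 (3 adjusted over the list alone; 9.81e-06). The adjusted p were 0.274, 0.274 and 0.281 with an estimated correlation. Among markers of other cell types, Kupffer cell and macrophage markers had 3 of 20 lower (6 adjusted over the list alone; camera 0.000485, 0.492 with an estimated correlation), with Gpnmb at -2.70 and Trem2 at -1.11. T, NK and B cell markers had 2 of 11 lower (2 adjusted over the list alone), with Ms4a1 of B cells at -2.02, and at -1.26 (adjusted p = 0.122) without WT 1. Camera called that list lower (adjusted p = 0.0303), and the call was lost with adjusted p = 0.586 with an estimated correlation, 0.134 without WT 1 and 0.0641 without KO 5. The KO means of Gpnmb and Ms4a1 were 0.3708 and 0.2772 CPM, so the sizes of their falls are uncertain. Lyve1 and Pecam1 fell by 1.41 and 0.80 among 16 sinusoidal endothelial markers (3 lower adjusted over the list alone), a list that camera did not call (median -0.12, adjusted p = 0.125). Alb, albumin, fell by 0.80 (SE 0.21), the 1 of 19 hepatocyte secretory products that passed.

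Of the insulin signalling list 1 of 25 genes passed in KO against WT, Igfbp1, an insulin-repressed binding protein, which fell to 94.98 ± 31.7 from 219 ± 62.0 CPM (SD, n = 5, edgeR adjusted p = 0.0142; 1 adjusted over the list alone). With the clock index its log2 change was -0.63 and it no longer passed (adjusted p = 0.477). The 1 of 17 gluconeogenesis genes that passed was Gk, glycerol kinase, which fell by 0.71 (SE 0.16), and Hk1 fell by 0.45, the 1 of 22 glycolysis genes that passed (2 lower adjusted over the list alone). Of 15 glycogen genes 3 fell, among them Pgm2 (-0.91), and 1 rose (the same count adjusted over the list alone; median -0.07, camera adjusted p = 0.340). In the thioredoxin system of 21 genes Txnrd2 rose by 0.35, Srxn1 fell by 0.55 and Txnip fell as given above (the same count adjusted over the list alone). In cholesterol synthesis Tm7sf2 rose by 0.67 and Dhcr7 fell by 0.66 among 25 genes (1 higher and 3 lower adjusted over the list alone), while 3 of the 25 had a positive log2 change and the median was -0.42. Camera called that list lower (adjusted p = 0.00486), and the call was lost with adjusted p = 0.731 with an estimated correlation and 0.124 without WT 2 and 0.0654 without KO 1. Of 24 xenobiotic metabolism genes 7 fell, among them Cyp3a11 (-2.54) and Ugt1a9 (-2.04), and 1 rose (6 higher and 10 lower adjusted over the list alone; camera adjusted p = 0.208). Igfals rose by 0.92 in the growth hormone list, where 2 of 13 rose and 1 fell (3 and 3 adjusted over the list alone), and the antigen transporter Tap1 rose by 0.64. Of 17 pericentral genes 3 rose, among them Slc1a2 (0.70) and Rnf43 (0.96), and 0 fell (5 adjusted over the list alone; camera adjusted p = 0.00377, and 0.274 with an estimated correlation). Of 17 periportal genes 4 fell, among them Ctsc (-1.03), and 0 rose (5 adjusted over the list alone; camera adjusted p = 0.000874, and 0.492 with an estimated correlation). The clock genes Dbp and Ciart rose by 1.09 (SE 0.24) and 0.67, with all 5 KO libraries above all 5 WT libraries for Dbp, the 2 of 19 clock genes that passed (4 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.176). Camera called 15 of 38 lists in KO against WT and 0 with an estimated correlation. Of the lists called, cholesterol synthesis, interferon response, Kupffer cell and T, NK and B cell lists did not pass fry (adjusted p = 0.246, 0.205, 0.0908 and 0.129). The others did, with fry adjusted p of 0.0164 to 0.0493.

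The count of 939 was 294 against a fold of 1.2 and 1505 with DESeq2, and 1542 without WT 1, C247S KI 3 and C247S KI 5, which were left out after seeing the data. It was 523 without WT 4, 521 without KO 2, 572 without KO 3, 611 without KO 4 and 546 without KO 5, and with a clock index as a covariate, added after seeing the data, it was 91, with Txnip itself no longer past the threshold (-1.12, adjusted p = 0.174). The index nearly separated KO from WT libraries, so that fall cannot part clock phase from genotype. With that index the values of Pdk4, Hmox1, Igfbp1, Gk, Tm7sf2, Dhcr7, Tap1, Rnf43, Dbp, Ciart and Cdkn1a moved by over 1.5 times, and of these Cdkn1a kept its call (-1.64). Among the genes named here Mup14, Mup12, Txnrd2, Srxn1, Hmox1, Hk1, Tm7sf2, Dhcr7, Atf3, Ms4a1, Alb and Ciart lost their call without at least 1 library, with the highest adjusted p for Ms4a1 without WT 1 (0.122). Under at least 1 other alternative set beforehand, the calls of Mup14, Txnrd2, Srxn1, Hmox1, Hk1, Tm7sf2, Dhcr7, Atf3, Ms4a1, Alb, Ciart, Gk, Cxcl1, Cyp2a4, Cyp2b13 and Gsta1 were lost, the last 4 of them with limma-voom alone and Gk against a fold of 1.2 alone. The camera calls of the interferon, T, NK and B cell, adipose, periportal and female-biased lists were lost with the clock index, and that of the T, NK and B cell list also without WT 1, C247S KI 3 and C247S KI 5.

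Between KO and C247S KI livers 1427 genes passed the edgeR threshold, 613 higher and 814 lower in KO. Cholesterol synthesis and lipogenesis genes were lower in KO. Sqle fell by 3.33 (SE 0.39), and Dhcr7 and Hsd17b7 changed by -1.74 (SE 0.20) and -1.37 (SE 0.18). Of the list, 19 of 25 cholesterol synthesis genes fell and 0 rose (21 adjusted over the list alone; camera adjusted p = 6.48e-27, and 0.267 with an estimated correlation). Scd1 fell by 4.66 (SE 0.48, edgeR adjusted p = 5.92e-05), and Acacb and Fasn, fatty acid synthase, changed by -2.78 (SE 0.32) and -1.68 (SE 0.28), with 12 of 20 lipogenesis genes lower and 1 higher (14 and 1 adjusted over the list alone; camera 5.75e-10, and 0.302 with an estimated correlation). Scd1 varied among C247S KI libraries, from 2623 to 15479 CPM.

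**Figure D3:**
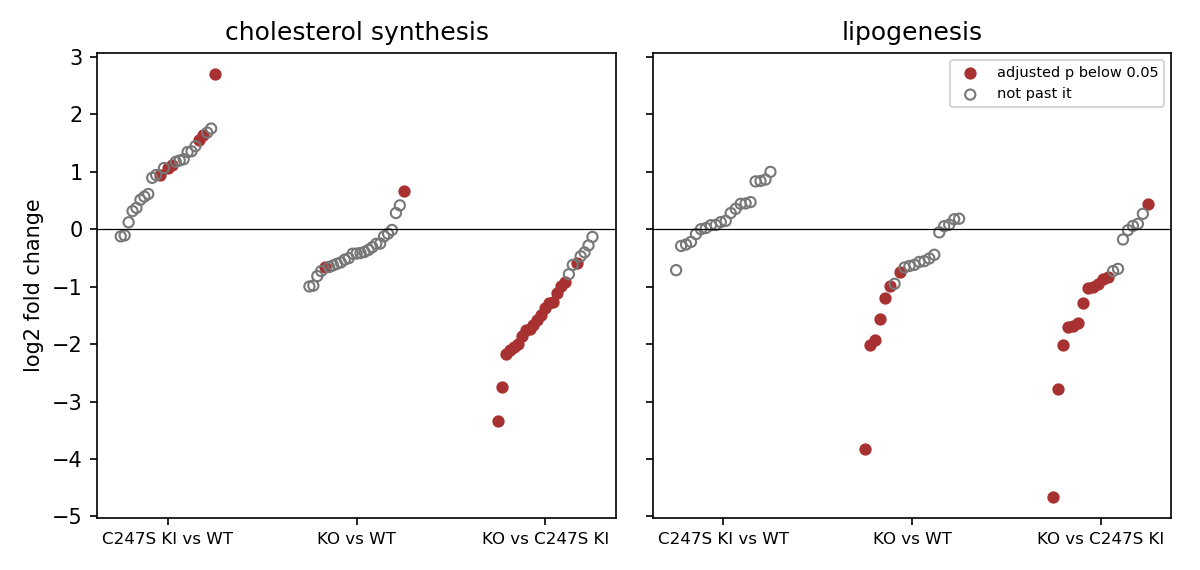
Log2 fold change (vertical axis) of each measured gene of the cholesterol synthesis list and the lipogenesis list in the 3 comparisons, ordered within a comparison; filled points passed an edgeR adjusted p of 0.05 over all genes and open points did not. Of 25 cholesterol synthesis genes 6 rose in C247S KI against WT and 19 fell in KO against C247S KI.

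Acute-phase genes were lower in KO than in C247S KI. The log2 changes of Saa2, Saa1, Lcn2 and Il1rn were -6.97 (SE 1.36), -5.77 (SE 1.03), -3.96 and -1.44, and 11 of 27 genes of the list fell and 0 rose (13 adjusted over the list alone; camera adjusted p = 0.000242, and 0.404 with an estimated correlation). In C247S KI 3 Saa1 stood at 24631 CPM against 447.5 to 3357 in the 4 other C247S KI libraries, and without that library Saa1, Saa2 and Lcn2 stood at -3.58, -3.94 and -2.26 and kept their calls. Saa1 and Saa2 are near-identical copies, so the division of reads between them is uncertain. Chrna4, Aqp4, Cyp2a22 and Tff3 changed by -5.85, -4.97, -4.94 and -4.84 (SE 0.884, 0.905, 0.911 and 0.919). Their KO means were 0.125, 0.0607, 0.322 and 0.774 CPM, and at such low levels the sizes of the falls are uncertain. Hist1h2al rose by 6.64, Obp2a by 3.34, Serpina9 by 2.75, Gbp2b by 2.56, Onecut3 by 2.48 and Plcd3 by 2.23. The C247S KI means of Hist1h2al, Serpina9, Gbp2b and Onecut3 were 0.067, 0.2225, 0.2024 and 0.2568 CPM, so the sizes of those rises are uncertain too.

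In the insulin signalling list Igfbp1 changed by -2.04 (SE 0.28) and Trib3 rose by 1.64 (SE 0.30) in KO against C247S KI, and 2 of 25 genes rose and 2 fell (2 and 4 adjusted over the list alone). With the clock index Igfbp1 was at -1.21 (adjusted p = 0.316) and Trib3 at 0.47 (adjusted p = 0.764), and neither passed. Of 17 gluconeogenesis genes 2 fell, Gk (-0.87) and Pck2 (-0.95), and 1 rose (2 higher and 3 lower adjusted over the list alone). Hk2 (-1.41) was the 1 of 22 glycolysis genes and Pgm2 (-0.90) the 1 of 15 glycogen genes that passed (1 lower, and 1 higher and 2 lower, adjusted over the list alone). In fatty acid oxidation 3 of 35 rose and 5 fell (6 and 6 adjusted over the list alone), and Pdk4 and Fgf21, a fasting hormone, changed by -3.48 and -1.71. With the clock index Pdk4 was at -1.52 and did not pass (adjusted p = 0.610). In the thioredoxin system 3 of 21 genes rose, including Txnrd2 (0.43) and Prdx6 (0.55), and 1 fell, Txnip (the same count adjusted over the list alone). Of 23 NRF2 targets 5 fell, among them Hmox1 (-1.34), and 0 rose (5 adjusted over the list alone; camera adjusted p = 0.0152, and 0.559 with an estimated correlation and 0.0518 without C247S KI 1). Of 24 xenobiotic metabolism genes 7 rose, among them Cyp2a5 (1.83) and Cyp2c37 (1.41), and 3 fell (7 and 4 adjusted over the list alone; median 0.04, camera adjusted p = 0.123). Cyp1a2 of the pericentral list rose by 1.33 (SE 0.24), with 5 of 17 pericentral genes higher and 0 lower (7 adjusted over the list alone; camera adjusted p = 7.58e-05, and 0.292 with an estimated correlation). Of 17 periportal genes 5 fell, among them Ctsc (-0.90), and 0 rose (6 adjusted over the list alone; camera adjusted p = 0.00530, and 0.559 with an estimated correlation and 0.0619 without C247S KI 4), and with the clock index the direction of that list turned (adjusted p = 0.744). Hsd3b7 rose by 0.55 among 19 bile acid genes, of which 2 rose and 0 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.0161, and 0.559 with an estimated correlation, 0.135 without C247S KI 3 and 0.0627 without C247S KI 5). Ndufs7 rose by 0.55, Tap1 by 0.82 and Igfals by 0.87. mt-Nd3 fell by 1.32, with the uncertainty given for C247S KI against WT.

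The clock list of 19 genes had 6 higher and 4 lower in KO against C247S KI (the same count adjusted over the list alone), with Dbp rising by 1.59 (SE 0.24) and Arntl changing by -1.61 (SE 0.30). Of 19 male-biased genes 4 rose, among them Susd4 (1.27), and 1 fell, Selenbp2 (-4.15), with 9 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000117, and 0.559 with an estimated correlation). Selenbp2 lies within 5 Mb of Txnip. Of 10 female-biased genes 2 fell, among them Cyp17a1 (-2.39), and 0 rose (5 adjusted over the list alone; camera adjusted p = 0.00491, and 0.464 with an estimated correlation). Of 4 genes listed as differing between mouse substrains 2 rose and 2 fell (the same count adjusted over the list alone): Nnt rose by 1.28, Wdfy1 rose by 1.45 and Entpd4 fell by 0.89. Acp6 rose by 0.57. Of 22 cell cycle genes 3 fell, among them Cdkn1a (-2.85), and 0 rose (4 adjusted over the list alone; camera adjusted p = 0.000117, and 0.464 with an estimated correlation). Markers of macrophages, endothelium and red cells did not move one way: Cd9 (-0.65), Lyve1 (-1.46) and Slc4a1 (-0.98) passed, but 12 of 20, 11 of 16 and 5 of 8 members had positive log2 changes, with medians of 0.10, 0.29 and 0.27 (camera adjusted p = 0.971, 0.554 and 0.804). Camera called lower the bile duct markers (2 of 9 genes lower, Spp1 at -1.48; adjusted p = 0.00530), the stellate cell and fibrosis markers (1 of 22, Col4a1 at -1.19; 0.00530) and the adipose markers (3 of 5, Cfd at -3.76 and Fabp4 at -1.44; 0.0154). Those calls were lost with adjusted p = 0.464, 0.612 and 0.302 with an estimated correlation, and that of the fibrosis list also without KO 5. Alb, albumin, fell by 0.80. Camera called 16 of 38 lists and 0 with an estimated correlation. The cholesterol synthesis, lipogenesis, lipid droplet, acute-phase, bile duct, adipose, pericentral and cell cycle lists passed fry (adjusted p of 0.00537 to 0.0307). The other lists that camera called did not, with fry adjusted p of 0.0519 to 0.180.

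The count of 1427 was 519 against a fold of 1.2. It was 830 without C247S KI 1, 2280 without C247S KI 3, 855 without C247S KI 5, 784 without KO 2, 948 without KO 3, 787 without KO 4 and 939 without KO 5, and with the clock index it was 61. Every KO library had a higher index than every C247S KI library, so that fall cannot part clock phase from genotype. With that index the values of Onecut3, Hmox1, Igfbp1, Trib3, Gk, Sqle, Pdk4, Fgf21, Hsd3b7, Cyp2a5, Tap1, Alb, Slc4a1, Dbp, Arntl and Cdkn1a moved by over 1.5 times, and of these Sqle and Cyp2a5 kept their calls. Txnip, Hk2, Ndufs7, Alb and Slc4a1 lost their call without at least 1 library, with the highest adjusted p for Slc4a1 without C247S KI 1 (0.135). Under at least 1 other alternative set beforehand, the calls of Txnip, Hk2, Ndufs7, Alb, Slc4a1, Cd9, Hsd3b7, Prdx6, Txnrd2 and Cyp2a22 were lost, that of Txnip against a fold of 1.2. The camera calls of the NRF2, lipid droplet, interferon, cholangiocyte, adipose, male-biased and female-biased lists were lost with the clock index, beside the periportal list that turned. Without WT 1, C247S KI 3 and C247S KI 5, left out after seeing the data, Ndufs7 and the bile acid list lost their calls.

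Across genes, the log2 changes of KO and C247S KI against WT correlated with Pearson's r of 0.258; genes are not independent replicates. Unchanged groups simulated against the shared WT controls gave a mean r of 0.5, and the observed covariance of 0.042 stood beside 0.039 in the simulation. With the WT libraries split in 2 and 3 so that no control was shared, the mean r was 0.015. Tm7sf2 was called higher in both mutants and Cyp2b13 lower in both, and Dhcr7 was called higher in C247S KI (1.07) and lower in KO (-0.66). In both comparisons Cyp2b13 overlapped between the mutant and WT libraries. With the numbers of calls seen, independent calls would give 0.23 genes higher in both and 0.13 lower in both. Unchanged groups simulated against the shared controls gave means of 0.05 genes higher in both, 0 lower in both and 0 in opposite directions. Groups without changes hold few calls by construction, so that overlap near 0 does not make the shared genes an excess. Split controls gave means of 0, 0.15 and 0.2.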

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

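Among the tests given here, the share of sequence between mt-Nd3 and Gm28438, the clock index adjustment and the removal of the genes farthest off in C247S KI 3 were set out before their results were seen, though the drop in the count of genes with the clock index had been seen by then, and the others were chosen after. Over 102 groups of 5 libraries tested for a value far from the others, 4 were found where chance gives about 5.1: Aqp4 in C247S KI 2 (2.18 on the log2 CPM scale), Cyp2a22 in WT 1 (1.86) and in KO 5 (-2.31), and Tff3 in WT 1 (3.84). Among the transcripts outside the annotation used, which enter no comparison of the report, 288 were abundant enough to test, and 1 was changed in C247S KI against WT, 0 in KO against WT and 2 in KO against C247S KI.

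mt-Nd3 was higher and Gm28438 lower in all 5 C247S KI libraries than in all WT and KO libraries. Higher mitochondrial transcription is argued against, since the 12 other mitochondrial genes had a median log2 change of 0.12, and at most 0.31. Reads divided between near-identical sequences may account for the pattern: 98.1% of the 31-base words of mt-Nd3 also occur in Gm28438, the 2 sequences differ at 1 of 345 bases compared, and the sum changed by -0.03 on the log2 scale. A variant in the mitochondrial genome that sets the C247S KI line apart from the WT and KO lines is a candidate cause of the shift. Gm28438 took at most 4.27% of the summed CPM in C247S KI and 63.99% to 71.22% in the WT and KO libraries. C247S KI counts thus went mostly to the reference mt-Nd3 and those of WT and KO mostly to its copy. Which line would carry the variant was not tested, reads were not used here, and the line cannot be told apart from the genotype. No biological explanation by the C247S change itself was tested.

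The 939 genes of KO against WT could come from the loss of Txnip, from collection at another time of day, from library size or from genetic differences between the lines. Library size is argued against, as the KO totals (median 21.05 M counts) overlapped those of WT. Clock phase could not be decided with the clock index, which was 2.62 to 3.55 in KO and 1.46 to 2.62 in WT libraries. Its slope therefore came from differences within groups, and an effect of time shared by a whole group may not be removed. With the index as covariate the median signed change of the called genes went from 0.72 to 0.67 (a ratio of 0.925), and all 939 kept their direction. Dbp went from 1.09 to 0.26, but it is itself a gene of the index. Calls fell to 91 as the median SE grew from 0.169 to 0.236, and a noisy index adjusts incompletely, so clock phase stays open. Genetic differences of the KO line may contribute, since 17 of 109 genes within 5 Mb of Txnip were called and Nnt rose by 1.05, but neither says how many of the 922 genes elsewhere depend on them, nor is the loss of Txnip excluded, and any cohort or batch shared by the KO libraries, whose titles carry numbers from a separate range, cannot be told apart from the genotype.

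Exchanging C247S KI 3 with KO 1 gave 1348 genes against 1427 with the labelled groups, which points to a structure of the samples. A mislabelled pair is argued against, because Gm28438 was at 13.9 CPM in C247S KI 3 and 513.7 in KO 1, and Hist1h2al at 0.057 and 6.15 CPM, each with its labelled group. Both genes were chosen after their values were seen, as genes that keep the labelled groups apart. Txnip, set beforehand, does not settle the pair, since C247S KI 3 lay within its KO range. An acute-phase state of C247S KI 3, where Saa1 reached 24631 CPM, could make that library less like its group, but without the 1000 genes farthest off in it the exchanged groups still gave 83.3% of the labelled count, against 94.5% with all genes. This decides neither way, and no biological explanation was tested.

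Chance as the source of the counts was examined with 100 of the 126 splits of the 10 libraries of each comparison. For KO against WT 1 split, the real one, gave as many as 939 genes and the highest of the others gave 1, and for KO against C247S KI 1 split gave as many as 1427 and the highest of the others gave 1348. For C247S KI against WT 4 of the 100 splits drawn, the real one included, gave at least the 12 genes seen, and the highest of the others gave 37, from exchanging WT 1 with C247S KI 5. In each comparison the share is under 0.05 among the splits drawn but could pass it with those not drawn, and that limit was set after the values were seen. In the comparisons with KO no other split drawn reached the real count, which speaks against chance only as far as the splits drawn go. For the 12 genes of C247S KI against WT chance is not excluded. The 37 genes are several times the real count, which points to a structure of the samples that the genotype does not follow.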

How the results depend on the processing

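The clock index covariate and the fit without WT 1, C247S KI 3 and C247S KI 5 were added after seeing the data. For C247S KI against WT the 12 genes became 65 with DESeq2, 20 with no count filter, 6 with only the 2 groups, 7 against a fold of 1.2, 28 with the clock index and 4 to 24 without each library; for KO against WT the 939 became 1505 with DESeq2, 294 against a fold of 1.2, 91 with the clock index, 1542 without the 3 libraries and 521 to 928 without each library; for KO against C247S KI the 1427 became 519 against a fold of 1.2, 61 with the clock index and 784 to 2280 without each library. A fold minimum lowers a count by construction; for the others the cause was not tested. With the replicate block, which the numbers did not bear out as pairs (r of deviations -0.141 to 0.381; 4 of 15 libraries correlated best with their own number), the counts were 6, 1046 and 1594. Txnip in KO against WT lost its call only with the clock index (-1.12, adjusted p = 0.174; range over all alternatives 8.70e-05 to 0.174). Lists called numbered 11, 15 and 16 in the 3 comparisons, 0 in each with an estimated correlation, and 1, 12 and 9 with fry; they were 17, 16 and 14 with the clock index, which ended 1, 5 and 7 of the calls and turned 1 in KO against C247S KI, and 17, 20 and 19 without the 3 libraries, which ended 2, 1 and 1. The periportal list in KO against C247S KI turned direction with the clock index (adjusted p = 0.744; the cause was not tested). The correlation of the mutants' changes was 0.258, 0.015 with split WT controls, 0.174 with a stricter count filter and 0.212 to 0.355 without each library. Of the 12, 58 and 59 named genes that passed in the 3 comparisons, 8, 12 and 5 lost their call without at least 1 library, 7, 16 and 10 in at least 1 other alternative set beforehand, 0, 44 and 48 with the clock index and 7, 1 and 1 without the 3 libraries, and 0 reversed. With only the 2 groups KO against WT gave 1291 genes and KO against C247S KI 1279. Genes at a few counts are limited by depth.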

Other observations

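The tests in this part were planned as list tests; their members are described here only as values. In KO against WT 0 of 22 urea cycle and amino acid catabolism genes and 0 of 49 nuclear oxidative phosphorylation genes passed the edgeR threshold (camera adjusted p = 0.699 and 0.405), and the median log2 changes were -0.03 and 0.04. In KO against C247S KI the nuclear oxidative phosphorylation list passed camera as higher (adjusted p = 1.06e-05, and 0.702 with an estimated correlation), with 47 of 49 members positive and a median of 0.23, and 1 member passed over all genes (0 adjusted over the list alone). Interferon response genes were higher in KO than in both other groups by camera (adjusted p = 0.0106 against WT and 0.00311 against C247S KI), with 2 and 5 of 28 genes past the threshold and 0 lower (4 and 5 adjusted over the list alone), and the calls were lost with adjusted p = 0.586 and 0.559 with an estimated correlation, and without KO 5 (adjusted p = 0.217 against WT and 0.0564 against C247S KI).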
